A study of Drosophila melanogaster with 4 samples.

How the data were processed

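The series is a ChIP-seq experiment on whole Drosophila melanogaster embryos of 0 to 8 h, from a strain carrying yellow, cinnabar, brown and speck mutations. ChIP-seq sequences the DNA that an antibody pulls out of cross-linked chromatin. The antibody was a rabbit polyclonal serum raised against the N-terminus of TCF, the protein of the gene pangolin, which is the fly member of the TCF/LEF family and the DNA-binding end of the Wingless (Wnt) signalling pathway. The labels list 2 ChIP libraries and 2 input libraries, numbered as replicates, the input being chromatin DNA taken without the antibody. The labels do not say whether replicates came from separate collections. The collection protocol in the labels also mentions a later egg-laying window. The stage label of 0 to 8 h was used here.

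The values analysed were 1 peak list for the whole series. Per the file headers, its coordinates are on FlyBase release 5, and its feature source is MACS, a caller that looks for stretches with more ChIP reads than expected. Per the submitters' processing notes, CASAVA 1.7.0.2, CASAVA 1.7.0.3, BWA, MACS2 and the build BDGP5 were used, without their roles. The calling threshold, the read filters and whether the replicates were pooled before calling are not given in the sources used here. Each peak has a start, an end and 1 score, deposited by the authors without a name or scale. No summit, read count or value per library was analysed here, so the depth of each library is unknown and no difference between ChIP and input libraries or between replicates could be tested.

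The scale of the score was read from its values. At low values the scores fell on discrete steps, and expected values from 1 to 400 were searched for the one at which the scores equal -log10 of the upper tail of a Poisson distribution at a whole-number pileup. With an expected pileup of 71.7, 4345 of the 4589 scores (94.7%) matched within 0.01, against 18.4% under the best other expected value at least 1% away. The matching peaks therefore have an implied pileup, known to within 1 because the tail could include or exclude the observed value, and an implied fold over the fitted expectation. For the other 244 peaks (5.32%) no fold is given. Exact Poisson 95% intervals of these folds cover counting error only, and the pileup is the value that the caller scored, so it is high by selection.

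Counts of peaks per arm on 2L, 2R, 3L, 3R, 4 and X were compared with 10000 random distributions of the same number of peaks over the arms. Arm length was taken as the end of the last peak, since no sequence of release 5 was used here. This length can only be too short, which raises the density, and a given shortfall weighs most on the short chromosome 4. The alternative length, between first and last peak, is shorter still and does not test this bias. Distances from each peak midpoint to the nearest other midpoint were compared with 1000 placements of the same widths, without overlap, within each arm. Score and width were compared by Spearman's rho with 100000 permutations. Medians of score and width were compared between sets of peaks by 10000 permutations, with bootstrap intervals from 2000 resamples. Shares of peaks were compared by Fisher's exact test. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each family. Peaks are not independent replicates, so these p-values describe this list and not the spread between embryo collections. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

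The scripts were tested on simulated data with 4544 peaks. A simulated 2-fold rise on arm 4 and a simulated 2-fold fall on X were each found in 200 of 200 runs, and 11 of 200 runs without an effect gave a call on any arm. These runs drew peaks independently, as the arm test itself assumes. They check the script and do not give the rate of false calls for grouped peaks. Simulated clustering was found in 20 of 20 runs, with 1 call in 20 runs without it. The fitted expected pileup was within 0.0117% of the true value in 3 simulations.

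Before the data were examined, the groups, tests, alternatives and the rule for named items were fixed. The rule named the 10 peaks with the highest score, the 5 widest peaks and the 5 windows of 100 kb with the most peaks, by coordinates, if no annotation of the files' release was at hand. The gene table at hand is on release 6, and coordinates were not converted between releases. The planned comparisons with genomic features, gene lists and sequence motifs were therefore not run, and no peak is assigned to a gene. The alternatives kept the 50% or 25% of peaks with the highest score, merged neighbouring peaks, changed the arm length or restricted random peaks to windows that hold a peak. The planned restriction to such windows of 1 Mb removed 0 of 122 windows, so a restriction to windows of 100 kb, which removed 275 of 1189, and a placement that kept the number of peaks in each 1 Mb window were added after the data were seen. The comparisons of medians between sets of peaks, the shares compared by Fisher's exact test and the density by quartile of score were also added after the data were seen. Bootstrap intervals of the X to autosome density, which resample 1 Mb windows, used 10000 resamples.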

Results

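The series asked where TCF, the nuclear effector of Wingless signalling, occupied chromatin in embryos of 0 to 8 h. The deposited list held 4589 peaks that covered 3228 kb on 12 sequences of FlyBase release 5. Of these, 4544 peaks lay on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X, and 45 lay on other sequences. The list is a single set for 2 ChIP and 2 input libraries, so no value in it has a replicate error, and the depth of the libraries is unknown.

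Most TCF peaks were narrow and weak, and a small set was strong. The median width was 500 bp (interquartile range 309 to 862 bp), and 169 peaks (3.68%) were wider than 2000 bp. The authors' score had a median of 16.3 (interquartile range 11.0 to 33.4) and ran from 6.02 to 904.92. On the scale fitted to the scores, the implied pileup of the 4345 matching peaks was 2.13-fold over the expectation at the median (interquartile range 1.90 to 2.75), with a range of 1.62-fold to 15.9-fold. The implied fold was under 3 in 3475 of these peaks (80.0%) and at least 5 in 244 peaks (5.62%). Higher-scoring peaks were wider. Spearman's rho was 0.80 across the 4589 peaks (permutation p = 1e-05, the smallest that 100000 resamples can give, two-sided), where peaks are not independent replicates. Among the 50% of peaks with the higher score, rho was 0.60. A higher pileup tends to stay above a calling threshold over a longer stretch. The relation is thus partly built into the peak calls and says little about TCF binding.

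**Figure D1:**
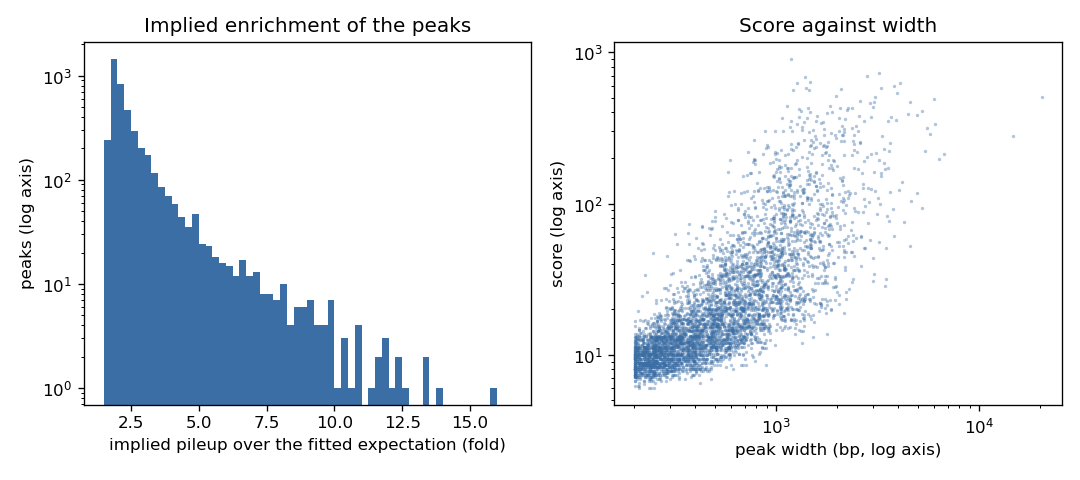
Left, number of peaks (log axis) by implied pileup over the fitted expectation, in fold, for the 4345 peaks whose score matched the fitted scale. Right, score against peak width in bp for all 4589 peaks, both on log axes, with 1 point per peak. The median implied fold was 2.13 and the highest 15.9, and score rose with width (rho 0.80).

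The TCF peak with the highest score, 904.92, lay on 3L at 18178558 to 18179740. Its implied pileup was 15.9-fold over the fitted expectation (95% counting interval 15.0 to 16.8). This fold and those below are over that single expectation and not over the input at each place. The second lay on 3R at 7603468 to 7606673, at 13.8-fold (12.9 to 14.7). The peak on 2L at 478859 to 481658 reached 13.4-fold (12.5 to 14.2), and that on 3R at 21462622 to 21464015 reached 13.3-fold (12.4 to 14.1). These intervals overlap one another, and only the interval of the 3L peak lies apart from them. The next peaks by score were 3L 21872546 to 21874015 at 12.6-fold (11.8 to 13.4), 2R 7083463 to 7087524 at 12.5-fold (11.7 to 13.3) and 3R 9808767 to 9810028 at 12.5-fold (11.7 to 13.3). The strongest X peak, at 2028292 to 2032111, ranked eighth with 12.1-fold (11.3 to 12.9). The remaining peaks of the 10 with the highest score lay on 2R, at 6158104 to 6159502 with 11.9-fold (11.1 to 12.7) and at 9452909 to 9456186 with 11.9-fold (11.1 to 12.7). Their genes are not assigned here, because the annotation at hand is on another release.

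Long stretches of TCF signal were found at a few places. The widest peak spanned 20.4 kb on 3L at 16004682 to 16025057, with an implied maximum of 10.9-fold (10.1 to 11.7), and it ranked 17 by score. The second widest spanned 14.7 kb on 2L at 3815365 to 3830103, at 7.68-fold (7.05 to 8.35). The remaining peaks of the 5 widest spanned 6.72 kb on 3L at 19034044 to 19040763 (6.54-fold), 6.38 kb on 2L at 14459246 to 14465630 (6.29-fold) and 6.08 kb on 2R at 20930933 to 20937017 (8.50-fold). None of the 5 widest peaks was among the 10 with the highest score.

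Among the arms, the deposited list was densest on chromosome 4 and sparsest on X, without a correction for the number of X copies. Chromosome 4, the small and largely heterochromatic autosome, held 135 peaks, or 108 per Mb (95% exact Poisson interval 90.3 to 128). X held 479 peaks, or 21.5 per Mb (19.6 to 23.5). The arms 2L, 2R, 3L and 3R held 42.5, 42.7, 42.4 and 38.4 peaks per Mb, and 41.3 per Mb when pooled. Relative to an even spread over the 6 arms, the count was 2.81 times the expected number on 4 and 0.56 times on X (permutation test, adjusted p = 0.0006 for each, from the smallest unadjusted p of 0.0002 that 10000 draws can give). The counts on 2L, 2R and 3L were 1.11 times the expected number (adjusted permutation p = 0.0012, 0.0008 and 0.0012), and that on 3R was 1.00 times (adjusted permutation p = 0.941). When 1 Mb windows rather than single peaks were permuted between arms, a test chosen after the data were seen, 4 and X kept their calls (adjusted permutation p = 0.00045 and 0.00024), and 2L, 2R and 3L lost theirs (adjusted permutation p = 0.483 for each). The call on 4 rests on 2 windows, a full one with 104 peaks and a short end window, up to 1.253 Mb, with 31. End windows shorter than 0.2 Mb were left out, which removed the end window of 2R, from 21 to 21.1467 Mb, with 18 peaks. For its length, that window was about as dense as the end window of 4, which was kept. Full and short windows had equal weight, so the call on 4 depends in part on this cut. With the least pileup on the large autosomal arms raised for an assumed 0.75 X copies per autosomal copy, the density on X relative to these arms went from 0.52 (95% bootstrap interval 0.40 to 0.65) to 1.11 (0.85 to 1.38), so the order of X and the autosomes depends on that correction. In the 50% of peaks with the higher score, the ratio was 2.13 on 4 and 0.67 on X (adjusted permutation p = 0.0006 for each). In the 25% of peaks with the highest score, the ratio on 4 was 1.51 (adjusted permutation p = 0.177), and that on X was 0.68 (adjusted permutation p = 0.0012).

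Strong peaks made up a smaller share of the peaks on 4, and a larger share of those on X, than on the large autosomal arms. The tests on these shares were chosen after the ratios in the 25% of peaks with the highest score were seen. They restate the same counts, so they are not independent support. All tests and intervals here treat grouped peaks as independent, so p-values may be too small and intervals too narrow. Scores on X were not corrected for the number of X copies. Per Mb, the 25% of peaks with the highest score were 1.41 times as dense on 4 (95% interval 0.83 to 2.24) and 0.65 times as dense on X (0.54 to 0.77). Of the peaks on 4, 13.3% (18 of 135, 95% exact Clopper-Pearson interval 8.10 to 20.3) were among the 25% with the highest score on the arms, against 24.7% (971 of 3930) on 2L, 2R, 3L and 3R (Fisher's exact test, adjusted p = 0.00412). On X the share was 30.7% (147 of 479, interval 26.6 to 35.0), above that on the same autosomal arms (Fisher's exact test, adjusted p = 0.00537). The median score was 19.4 on X and 15.9 on the 4 large autosomal arms, a difference of 3.44 (95% bootstrap interval 1.34 to 5.96, adjusted permutation p = 0.0006). On chromosome 4 it was 13.1, and the difference of -2.85 (interval -3.49 to -0.32) did not pass the test after adjustment over 6 comparisons of medians (adjusted permutation p = 0.0914). Widths on X and on 4 did not pass it either, with medians of 499 and 445 bp against 505.5 bp (adjusted permutation p = 0.773 and 0.215).

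**Figure D2:**
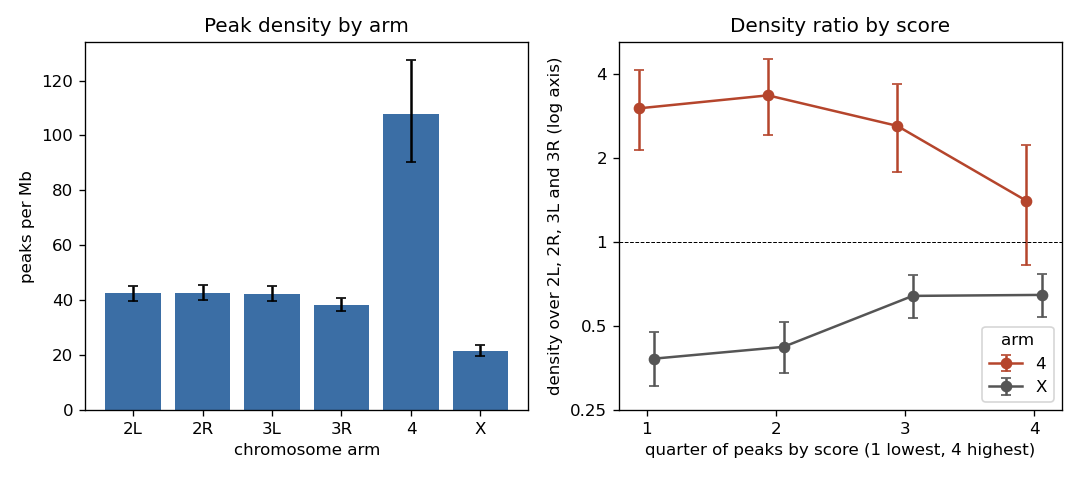
Left, TCF peaks per Mb on each chromosome arm, with exact Poisson 95% intervals as error bars. Right, ratio of peak density on 4 and on X to that on 2L, 2R, 3L and 3R together (log axis) in each quartile of peaks by score, with 95% intervals. All intervals treat grouped peaks as independent. From the lowest to the highest quartile the ratio was 3.02, 3.36, 2.61 and 1.41 on 4, and 0.38, 0.42, 0.64 and 0.65 on X.

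TCF peaks lay in groups along the arms. The median distance from a peak midpoint to the nearest other one was 2323 bp, against 9123 bp for randomly placed peaks (95% range of 1000 placements 8701 to 9560 bp, permutation p = 0.002, the smallest they can give). Another midpoint lay within 5000 bp for 2991 of the 4544 arm peaks (65.8%). Of 1189 windows of 100 kb, 275 (23.1%) held no peak, against 40 under random placement (permutation p = 0.002). At least 10 peaks were found in 105 windows, against 15 at random (permutation p = 0.002), and these held 1547 peaks (34.0%). After peaks closer than 1000 bp were merged, the median distance was 6492 bp, or 0.51 of that of as many random peaks (permutation p = 0.002). The random peaks were not merged, which raises this ratio by construction.

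The richest windows lay side by side on 2L. The window at 14400001 to 14500000 held 33 peaks that covered 43.8% of it, and the window at 14500001 to 14600000 held 31 peaks that covered 27.7%. The best peak in the first, at 14481654 to 14486882, had a score of 410.65 and ranked 32. The window on 3R at 17200001 to 17300000 held 30 peaks (29.9% covered). A further 3 windows tied with 26 peaks, at 2400001 to 2500000 on 2R, 900001 to 1000000 on 3R and 11400001 to 11500000 on 3R. At the scale of 1 Mb, the fullest windows were 0 to 1 Mb on 4 with 104 peaks, 0 to 1 Mb on 3R with 99 peaks and 14 to 15 Mb on 2L with 84 peaks. The emptiest was 0 to 1 Mb on 2R with 4 peaks, and the median of 116 full windows was 37 peaks.

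**Figure D3:**
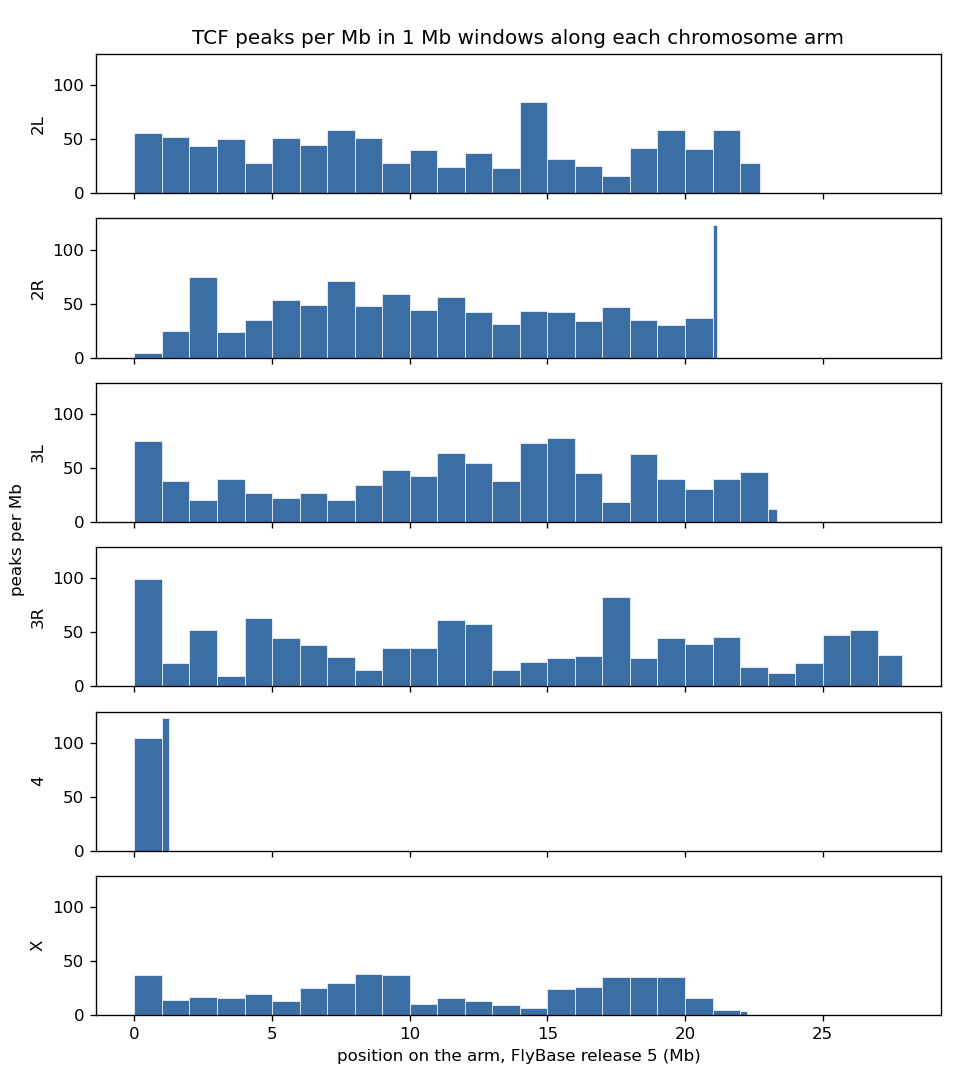
TCF peaks per Mb in windows of 1 Mb along each chromosome arm, by position on FlyBase release 5 in Mb. The last window of an arm is shorter and ends at its last peak. Chromosome 4 held 104 peaks in its first Mb, the first Mb of 3R held 99, and X held at most 38 in a window.

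Peaks on unplaced sequence had higher scores than those on the large autosomal arms. The 38 peaks on U and Uextra, which collect sequence not placed on an arm, had a median score of 43.1 against 15.9 on 2L, 2R, 3L and 3R, a difference of 27.2 (95% bootstrap interval 20.1 to 32.9, adjusted permutation p = 0.0006). Their median width was 397 bp against 505.5 bp, a difference of -108.5 bp whose bootstrap interval (-145.5 to -59) lies below 0, while the permutation test did not pass the threshold (adjusted permutation p = 0.215), so a difference in width is not settled. Scores were not compared at equal width, and the comparison of medians was chosen after the data were seen. The score departed from the fitted expectation in 4 of the 38 peaks, so most were scored against that single value. The number of copies of these sequences is not known and was not corrected for. A higher score here therefore need not mean more TCF. The test and intervals also treat peaks as independent. The other sequences were 2RHet with 4 peaks, 3LHet and 3RHet with 1 each, and the mitochondrial genome with 1, at 14591 to 14907 and a score of 62.88. The number of copies of the mitochondrial genome was not corrected for either.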

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

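All the values below rest on 1 peak list, and the merging of peaks within 5000 or 10000 bp, the permutation of 1 Mb windows and the placements of random peaks within 100 kb windows or with the count of each 1 Mb window kept were chosen after the data were seen. Of 49 values under alternatives, 28 were kept: they had the same direction and call or, for the number of peaks (4182 after merging within 200 bp, against 4589), stayed within 1.5 times the main count. The ratio on 3R, 1.002 as deposited, lay on the other side of 1 in 5 alternatives, none past the threshold: 0.984 and 0.939 in the 50% and 25% of peaks with the higher score, 0.972 and 0.965 with peaks closer than 1000 and 10000 bp merged, and 0.997 with the arm length between first and last peak. Keeping the 50% or 25% of peaks with the higher score left 2305 and 1161 peaks, with median widths of 837 and 1097 bp, by construction, since score and width go together; merging peaks closer than 200 bp gave a median width of 554 bp. The higher counts on 2R and 3L no longer passed the threshold in the 50% of peaks with the higher score (ratios 1.08 and 1.08) or in the 25% with the highest score (1.06 and 1.13), where that on 4 did not either (1.51). With peaks closer than 10000 bp merged, the ratios on 2L, 2R and 3L were 1.06, 1.09 and 1.04, and with 1 Mb windows permuted they were 1.11, 1.10 and 1.08, none past the threshold. Fewer peaks entered the tests of subsets and merged peaks, and the window test has fewer units. In the alternatives of the arm test, X stayed below 1 and past the threshold (ratios 0.55 to 0.80), but a correction for X copies, given under the other observations, moved its density relative to the autosomes above 1. The clustering ratio lay between 0.25 and 0.84, of which the value with random peaks in any 1 Mb window that holds a peak tests nothing, since each window held one. The ratios with merged peaks are raised by construction, since the random peaks were not merged. The planned comparisons with genomic features, gene lists and motifs, and their alternatives, were not run. No paired analysis was possible because the list holds no value per library, and for the same reason no replicate could be left out. The depth of the libraries is unknown, so weak or missing peaks cannot be read as absent binding.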

Other observations

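The tests on chromosome 4 of weak peaks and of the local background, the test on X and the tests on clustering with 100 kb or 1 Mb windows were chosen after the related values were seen. The test on clustering with merged peaks and the test on windows as long as chromosome 4 had their predictions written before their values were seen.

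TCF peaks formed long chains at a few places. With gaps of at most 5000 bp allowed, the 4544 arm peaks fell into 2337 groups, of which 1426 were single peaks and 158 held at least 5 peaks. These 158 groups contained 1188 peaks (26.1%), and 38 of the 100 peaks with the highest score, yet their median score was 14.63 against 17.96 for single peaks. The longest chain lay on 2L at 14423511 to 14520903, with 44 peaks over 97.4 kb, 55.8% of it covered, and a second chain of 17 peaks followed at 14527266 to 14567069. Other long chains were 27 peaks on 3R at 17234331 to 17297419, 24 peaks on 3R at 21822669 to 21868563, and 21 peaks on 3L at 14939130 to 14972835. Chromosome 4 had a chain of 16 peaks at 837383 to 872305, 23.2% covered, whose best score was 61.78. These places were named after their values were seen.

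Peak density near the centromere is described only, because its 2 Mb were not measured alike on all arms. On 2L, 3L and X they ended at the last peak, so a peak-free stretch beyond it was left out. On 2R and 3R they began at the first base, so such a stretch was counted. In these 2 Mb, 2R had 14.5 peaks per Mb (95% exact Poisson interval 9.71 to 20.8) against 45.6 on the rest of the arm, and X had 10.5 (6.50 to 16.1) against 22.6. On 3R the value was 60.5 (50.2 to 72.3) against 36.7, with 99 peaks in the first Mb and 22 in the second. On 2L it was 50.5 (41.1 to 61.4) against 41.8, and on 3L 37.5 (29.5 to 47.0) against 42.9. No test was run on these differences, and the Poisson intervals treat grouped peaks as independent, so a difference between arms is not settled.

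The grouping of peaks is not explained by the caller cutting single regions into adjacent pieces alone. After peaks closer than 5000 bp were merged, the median distance was still 0.84 of that of as many random peaks (permutation p = 0.002), against 0.25 before. Merging removed gaps under 5000 bp from the observed peaks but not from the random ones, which raises the ratio by construction. The rise therefore does not measure how much of the grouping came from cut regions. Empty 100 kb windows do not account for it alone, since placing random peaks only in 100 kb windows that hold a peak gave a ratio of 0.32 (permutation p = 0.002). Uneven density at the scale of 1 Mb does not account for it alone either, since keeping the number of peaks in each 1 Mb window gave a ratio of 0.28 (permutation p = 0.002). A candidate explanation for the rest is that regulatory regions are grouped along the genome, which was not tested, because no annotation of this release was used.

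The density on chromosome 4 is not explained by its short length, since 0 of 91 windows of the same length on the other arms held as many peaks as the 135 on 4, and the fullest held 107. An excess of weak peaks from a raised diffuse signal stays open, because the test was prompted by the highest quartile by score, where the density on 4 was 1.41 times that on the large autosomal arms (95% interval 0.83 to 2.24). The ratio was 2.61 (1.79 to 3.69) in the quartile below it and 3.02 (2.14 to 4.14) in the lowest. The excess is therefore not limited to the lowest quartile, although these intervals treat grouped peaks as independent. Scores in the quartile below the highest ran from 15.93 to 32.94, and a score of 32.07 implies 2.70-fold. Its peaks are thus also weak, and its ratio does not argue against this explanation. A local input background on 4 above the genome-wide expectation would not account for the excess under 1 condition. The caller must have scored such peaks against the raised local value, as MACS does by default. The score departed from the genome-wide expectation in 4 of the 135 peaks on 4 (95% interval 1.10 to 10.0 peaks), against 87.0 peaks above an even spread (65.2 to 112). The settings of the caller are not given in the sources used here. Since 94.7% of all scores matched 1 expectation, local values may hardly have been used. A background on 4 raised over the other arms but below that expectation would also leave the scores unchanged. The scores therefore cannot exclude a raised background on 4 in general. The design names no group that could give a biological explanation for chromosome 4, so none was tested.

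The low density on X could follow from fewer X copies in a mix of males and females, which would lower the reads on X against a single genome-wide expectation. In an even mix X has 0.75 times the autosomal copies, and when the least pileup on the autosomes was raised accordingly, from 116 to 155, the ratio of X to autosome density went from 0.52 (95% interval 0.40 to 0.65) to 1.11 (0.85 to 1.38). Both ratios count all 479 peaks on X, of which 7 had a score that did not match the fitted scale. The uncorrected count on the large autosomal arms includes 229 such peaks of 3930. The pileup of these peaks is not known, nor whether the autosomal ones reach the raised least pileup. The corrected ratio is uncertain to that extent. At a least pileup of 150, 200 or 300 on X the uncorrected ratios were 0.63 (0.47 to 0.80), 0.64 (0.46 to 0.86) and 0.78 (0.48 to 1.12). With the correction they were 1.40 (1.04 to 1.80), 1.32 (0.94 to 1.78) and 1.57 (0.95 to 2.31). These cuts are nested, so they are not separate tests. No corrected ratio lay below 1, and 1 of the 4 intervals lay past 1. The prediction for fewer X copies was that the interval holds 1 at every least pileup, which was not met, so the question stays open. The number of X copies in these embryos is also not known. Scores that departed from the fitted expectation were also rarer on X, at 1.46% (7 of 479) against 5.83% (Fisher's exact test, adjusted p = 2.29e-05). That test treats grouped peaks as independent. The sex of the embryos is given as unknown, and a true lower occupancy of X was not tested.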
